A study of Homo sapiens with 2 samples.

How the data were processed

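Gene expression was measured on Affymetrix 3' expression arrays in KG1 cells, a human acute myeloid leukaemia line with features of early progenitors. The cells had been electroporated with 1.98 µg of an siRNA against T-bet (group siRNA-Tbet) or of a control siRNA (group siRNAc), rested for 5 h and stimulated with interleukin-18 at 10 ng/ml for 12 h, per the labels. Total RNA was extracted with Trizol and 1 µg of it was converted to biotinylated cRNA, per the labels' protocols. Each group holds 1 array, so there is no replicate error for any value, and no p-value was computed.

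The deposited values are linear signal intensities, 1 per probe set and array. Per the submitters' processing notes they were made with MAS5, which combines the perfect-match and mismatch probes of a probe set into 1 intensity; a version is not given in the sources used here. Both arrays of deposited intensities had a trimmed mean (2% removed at each end) of 1000 in arbitrary units, so the arrays share a global scale, and no further normalization was applied in the main setting. MAS5 detection calls, scanner files and probe-level values were not used here. MAS5 subtracts mismatch signal probe set by probe set, which makes low intensities noisy, and fluorescence is compressed at the top of the scale, which understates differences there.

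Probe sets were named from the platform annotation supplied with the series, and symbols were updated through their Entrez gene numbers against the RefSeq annotation of GRCh38.p14. Of 54675 probe sets, 41097 had 1 gene, 1801 had several and were left out, and 11777 are unnamed here. Of the probe sets with 1 gene, 41043 matched the RefSeq table, and the others kept the platform's symbol. No genome coordinates were used. The 62 Affymetrix control probe sets were kept apart and read as a check on labelling and hybridisation.

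The signals were compared on the log2 scale as siRNA-Tbet over siRNAc. Each array's median over non-control probe sets (144 on the siRNA-Tbet array and 146 on the siRNAc array) served as a floor to which lower values were raised. A fold change against a floored value is a lower bound, given as "at least". This does not hold where the siRNA-Tbet signal lies between the floors of 144 and 146 and the siRNAc signal is floored. The floored ratio can then take the wrong sign, as for MAP2K6 (144.3 with siRNA-Tbet and 89.2 with siRNAc, floored log2 ratio -0.02). A probe set counted as measured when it lay above its array's median on at least 1 array. Each gene was represented by its probe set with the highest mean log2 signal, avoiding probe sets with the suffix _x_at (probes that can cross-hybridise) where the gene had any other. This left 12164 measured genes of 19775 on the array.

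The number of genes that differed at least 2-fold was counted by that fixed size. For 23 gene lists, the median log2 ratio of the measured members was placed among 10000 random lists of the same size matched on mean signal in 10 bins. A list was said to stand apart at percentile 2 or lower or 98 or higher. This describes these 2 arrays and is not a test of the treatment. A gene's own percentile was taken among the measured genes of its signal decile. The spread between probe sets of 1 gene (SD of the difference between the log2 ratios of its 2 brightest measured probe sets, divided by the square root of 2) was used as a measure of technical noise. It leaves out variation between cultures, RNA preparations and arrays.

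The gene lists, the thresholds, the alternatives and the rule for the genes named were fixed before the data were examined. The rule took TBX21 and IFNG; the 15 genes with the largest ratio in each direction among those above the 75th percentile of their brighter array whose measured probe sets all lay on the same side of 0; up to 10 genes per direction with 2 or more measured probe sets that all differed at least 2-fold; up to 4 members per list, those with the largest ratios; and the Affymetrix controls. For a list that stood apart, these list members came only from the side of its median, so members on the other side could not be named. Alternatives were median scaling, quantile normalization, removal of a lowess trend (span 0.3) of the ratio on signal, floors at the 25th and 75th percentile, no floor or filter, other choices of probe set, folds of 1.5 and 3, and other ways of matching and summarising lists. The use of each gene's second-brightest probe set was added after seeing the data.

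The procedure was tested on 20 simulated pairs of arrays drawn from the real mean signals of all 54675 probe sets, with the spread between probe sets as noise. Measured genes were selected anew in each draw. A list of type I interferon-stimulated genes shifted by -0.2 on the log2 scale was recovered in 100% of the draws, and 3% of 200 random lists stood apart without any shift. That shift is larger than any list median seen here (at most -0.18), so recovery of smaller shifts was not tested. The share of random lists follows from the bounds, as random lists were scored against random lists. Noise was drawn independently for each probe set, so genes that vary together were not simulated. Of 50 genes lowered by 1.5 on the log2 scale, 81% were counted as at least 2-fold lower, and of 50 raised by 1.5, 95.8% as at least 2-fold higher; the floor limits the first share. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.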

Results

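To find the genes whose expression depends on T-bet in a myeloid cell line, transcript levels were profiled in IL-18-stimulated KG1 cells that had received either an siRNA against T-bet or a control siRNA. T-bet, encoded by TBX21, is the transcription factor of type 1 lymphocyte responses, and IL-18 is a cytokine that induces interferon-γ. The data consist of 2 arrays, 1 for siRNA-Tbet and 1 for siRNAc, each with 54675 probe sets. Signals ran up to 69761 on the siRNA-Tbet array and 62673 on the siRNAc array, in arbitrary MAS5 units. The rank correlation of the 2 arrays over all non-control probe sets was 0.938. With 1 array per group, none of the differences below has a replicate check, and the number of arrays limits their precision. The spread between probe sets of the same gene, which covers technical noise only, fell with signal. It was 0.41 on the log2 scale in the dimmest of 10 bins of genes with several probe sets (median signal 228) and 0.12 in the brightest (median signal 11285).

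The targeted transcript was lower in the cells that received its siRNA. TBX21, read by its only named probe set, had a signal of 1839 with siRNA-Tbet and 3581 with siRNAc, a 1.95-fold difference that left 51.3% of the control signal. Its log2 ratio of -0.96 was the lowest among the 1217 genes of its signal decile, where the median was -0.04, and the technical spread at that signal was 0.18. IFNG, which encodes interferon-γ and is the best known T-bet target, was among the brightest genes on both arrays. Its signal was 31243 with siRNA-Tbet and 35136 with siRNAc, which is 11.1% lower (log2 ratio -0.17). Genes of its decile had a median log2 ratio of 0.04, and IFNG lay at percentile 4.8 among them. The technical spread at that signal was 0.12, and such high signals can be compressed.

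**Figure D1:**
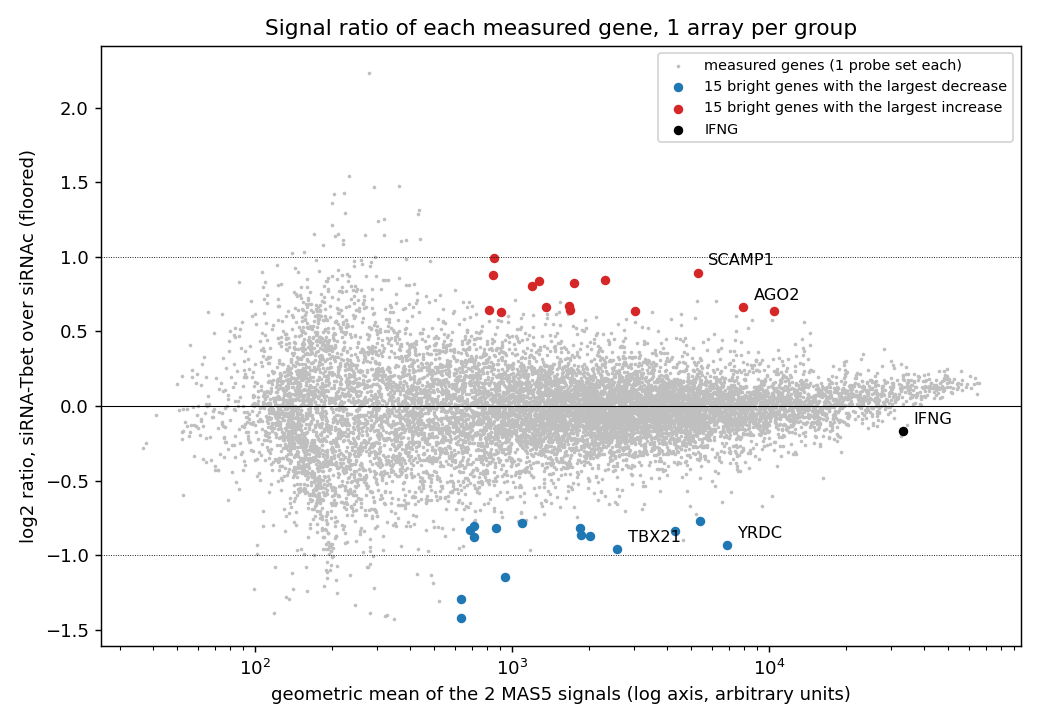
Log2 ratio of siRNA-Tbet over siRNAc (y axis) against the geometric mean of the 2 MAS5 signals (x axis, log scale, arbitrary units) for the 12164 measured genes, 1 probe set each and 1 array per group; values below each array's median were raised to it, and dotted lines mark 2-fold differences. TBX21 lies at -0.96 below the band of genes of similar signal, which widens towards low signal, and IFNG lies at -0.17 among the brightest genes.

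With low signals raised to each array's median, few genes differed strongly between the arrays. Of the 12164 measured genes, 95.1% differed by less than 1.5-fold. At least 2-fold differences were seen in 27 genes that were higher and 39 that were lower with siRNA-Tbet, and 13 and 21 of these, respectively, rest on a value at the floor. The floor sets these counts: they were 860 and 791 with a floor at the 25th percentile, 1873 and 1780 with none, and 0 and 0 at the 75th percentile. Among the 7557 genes with a signal above the 75th percentile, 3 were at least 2-fold lower and 0 were at least 2-fold higher. In simulated arrays with no change, the technical spread alone gave a mean of 8.9 genes 2-fold higher (range 3 to 16) and 9.6 genes 2-fold lower (range 4 to 20). That spread came from floored ratios and was held constant below the dimmest bin. The simulation can thus understate the noise of dim genes, and cannot show that the real counts exceed noise. The 2 brightest probe sets of a gene gave log2 ratios that correlated weakly across the 6155 genes with several measured probe sets (Pearson r = 0.15; genes are not independent replicates).

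The 15 bright genes with the largest decrease included TBX21, at rank 4 among the genes whose probe sets all lay on the same side. The 3 above it were SLC26A11, an anion transporter (signal 387 against 1037, 2.68-fold lower), PUS10, a pseudouridine synthase (405 against 993, 2.45-fold), and JAML, a leukocyte adhesion molecule (632 against 1398, 2.21-fold). The second probe set of PUS10 differed by only -0.12 on the log2 scale. YRDC, an enzyme of tRNA modification, was 1.91-fold lower (4966 against 9495), and its second probe set had a log2 ratio of -0.57. SUCNR1, the succinate receptor, was 1.79-fold lower (3230 against 5773). CA2, a carbonic anhydrase, was 1.83-fold lower and IGF2BP3, an RNA-binding protein, was 1.76-fold lower with -0.48 at its second probe set. SHCBP1 was 1.71-fold lower (4145 against 7085), and GPSM2, which orients the mitotic spindle, was 1.72-fold lower with -0.49 and -0.20 at its other probe sets. The others were ZNF385A, FAXDC2, SLCO4C1, CMIP and GTF2IP20, at 1.75-fold to 1.84-fold lower. CMIP had only -0.29 and -0.06 on the log2 scale at its other probe sets. GTF2IP20 is a pseudogene read by a cross-hybridising probe set and is uncertain. FER, a tyrosine kinase, was the only gene with 2 or more measured probe sets that all differed at least 2-fold in the same direction. Its log2 ratios were -1.01 and -1.17, at the low signals of 204 against 410 for the brighter one.

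The 15 bright genes with the largest increase were led by HLA-F-AS1, an antisense RNA (1198 against 602, 1.99-fold higher). SCAMP1, a membrane protein of the secretory pathway, was 1.86-fold higher (7201 against 3877), with log2 ratios from 0.39 to 1.30 at its 6 probe sets. SAR1B and SEC24A, both components of the COPII coat of vesicles leaving the endoplasmic reticulum, were 1.79-fold and 1.57-fold higher on the chosen probe sets, with only 0.38, 0.19 and 0.06 on the log2 scale at the others of SAR1B and 0.21 and 0.20 at those of SEC24A. Agreement in sign was part of the rule that picked these genes and so is no added evidence. AGO2, the Argonaute protein that loads siRNAs, was 1.58-fold higher (9970 against 6300) on its single measured probe set. GNB1, a G protein subunit, was 1.55-fold higher (13023 against 8382), with 0.22 and 0.36 at its other probe sets. XPR1, a phosphate exporter, was 1.77-fold higher, PYGB, a glycogen phosphorylase, 1.84-fold, SFT2D3 1.79-fold, TLN1, which encodes talin, 1.59-fold, and TLE4, a corepressor, 1.59-fold. Other probe sets had log2 ratios of 0.38 for XPR1, 0.60 and 0.17 for TLN1, and 0.71, 0.02 and 0.01 for TLE4. TPSB2, a tryptase, was 1.75-fold higher on a probe set that can also read its close paralogs and is uncertain. H1-2, THAP9-AS1 and AHNAK were 1.55-fold to 1.56-fold higher.

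Genes of the type 1 programme and of the interferon response had lower signals with siRNA-Tbet as groups, by small amounts. Of the 23 lists, 6 stood apart from random lists of matched signal, against 0.92 expected for lists of unrelated genes. Genes of one list can vary together between any 2 cultures, so this excess alone does not point to T-bet. The list of Th1 and natural killer effector genes had a median log2 ratio of -0.18, or 11.8% lower, at percentile 0.01. Of its 30 measured members, 23 were lower and 7 were higher, and 1 was at least 2-fold lower. That gene was CRTAM, a receptor of cytotoxic cells, at least 2.14-fold lower (115 against 309). HAVCR2, the inhibitory receptor TIM-3, was 1.54-fold lower with 3 of 3 probe sets in the same direction. LTA, encoding lymphotoxin-α, was 1.49-fold lower (1130 against 1681). SLAMF7 and PRDM1 were 1.53-fold and 1.54-fold lower on the chosen probe set, but 1 of the other probe sets of SLAMF7 and both of the others of PRDM1 were higher. The highest member of the list had a log2 ratio of 0.09, and only lower members were open to naming. The list no longer stood apart when the floor was at the 75th percentile (median -0.05), when only plain probe sets were used (median -0.05) or, in an alternative added later, with each gene's second probe set (median -0.0034, percentile 49.0, 13 genes). With the median over each gene's probe sets its median was -0.10.

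The interferon lists, which share no measured gene with each other or with the Th1 list, were also lower. The type I interferon-stimulated genes had a median log2 ratio of -0.12, or 8.0% lower, at percentile 0, meaning that none of the 10000 random lists was as low. Of their 48 measured members, 38 were lower and 10 were higher, and 0 differed 2-fold. IFIT2, IFIT1 and HERC5, which encode antiviral proteins, were 1.61-fold, 1.45-fold and 1.46-fold lower, with signals of 2532 against 4084, 2740 against 3966 and 855 against 1246. USP18, a negative regulator of interferon signalling, was 1.38-fold lower. The interferon-γ response genes had a median of -0.10, or 6.6% lower, at percentile 0.01, with 27 of 39 measured members lower and 12 higher. IL15, a cytokine that sustains natural killer cells, was 1.83-fold lower (233 against 426), with a log2 ratio of -0.79 at its other probe set. IDO1, which degrades tryptophan, was 1.58-fold lower (256 against 405), BATF2 was 1.42-fold lower and P2RY14 1.37-fold lower. The highest members had log2 ratios of 0.31 in the interferon-γ list and 0.12 in the type I list, and only lower members were open to naming. The type I list stood apart under every alternative fixed in advance, and the interferon-γ list under all but random lists without signal matching (percentile 2.31). With second probe sets the medians were -0.08 at percentile 4.0 for the type I list and -0.10 at percentile 2.2 for the interferon-γ list.

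Genes of the opposing T helper programmes did not stand apart in the main setting. The Th2 and Th17 list had a median log2 ratio of 0.07 over 12 measured members, at percentile 89.5, and 0.33 at percentile 98.4 over the 4 with a second probe set. GATA3, the master factor of Th2 cells, was 1.15-fold higher (1749 against 1515), with 3 of 3 probe sets on that side, and IL1RL1, the IL-33 receptor, was 1.21-fold higher, also with 3 of 3. IL5 had signals of 323 and 252, and IL13 of 190 and 257. Genes of MHC class II presentation had a median of 0.06 over 14 members, at percentile 91.0; CTSH was 1.37-fold higher and HLA-DMB 1.21-fold lower.

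**Figure D2:**
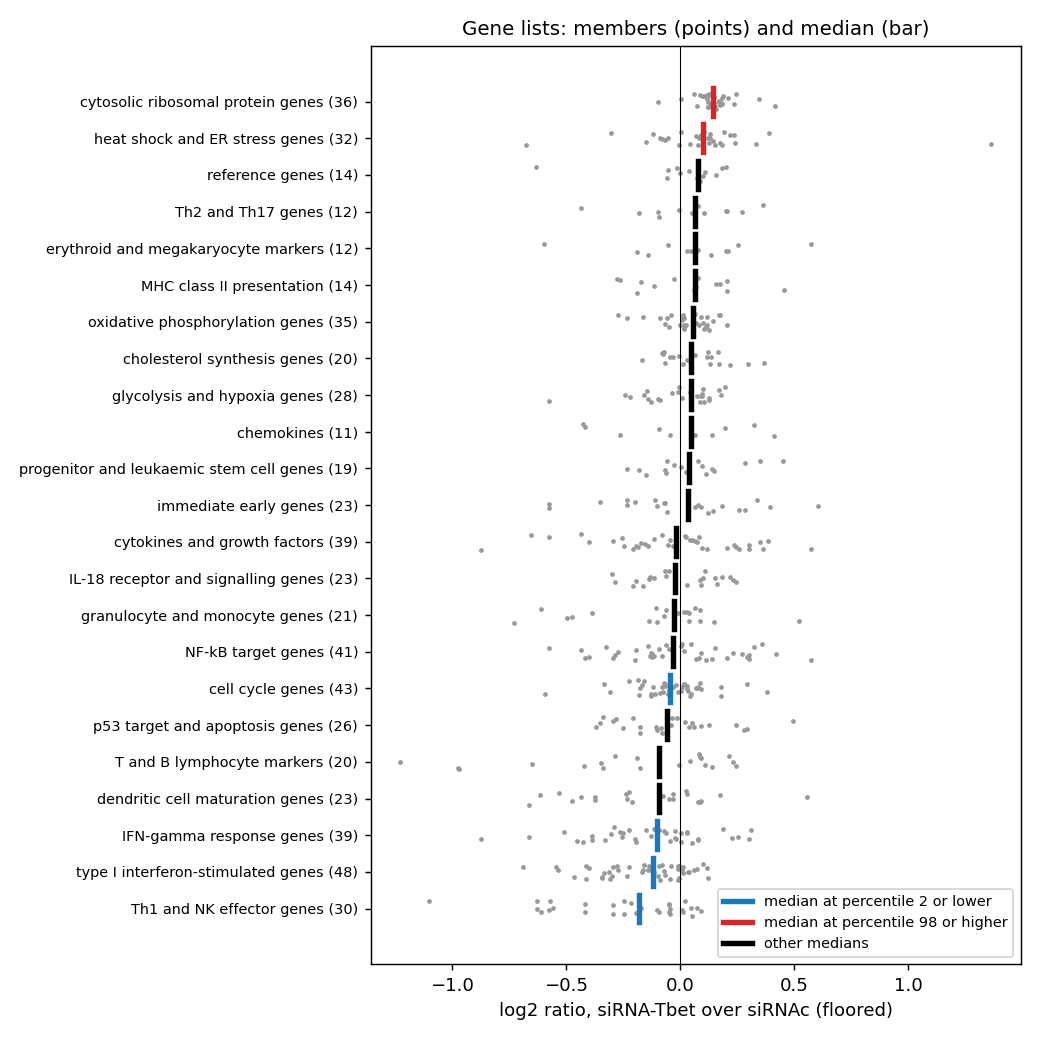
Log2 ratio of siRNA-Tbet over siRNAc (x axis) for the measured members (grey points) of the 23 gene lists (y axis, number of members in brackets) and their medians (bars, coloured where the median lies at percentile 2 or lower or 98 or higher among 10000 random lists of matched signal), from 1 array per group. The Th1 and natural killer, type I interferon and interferon-γ lists have medians of -0.18, -0.12 and -0.10, and single members overlap widely between lists.

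Lists of inflammatory genes and of the IL-18 receptor and its signalling did not stand apart in the main setting. The NF-κB target list had a median log2 ratio of -0.03 at percentile 32.4, with 20 of 41 members higher and 21 lower. TNFRSF9, a costimulatory receptor, was 1.34-fold higher, CD40 was 1.35-fold lower and IL23A was at least 1.49-fold higher. The chemokines had a median of 0.05 over 11 measured members at percentile 81.4. CXCL9 was 1.34-fold lower (975 against 1308), CCL4 was 1.33-fold lower (1027 against 1368), CXCL13 was 1.33-fold higher (214 against 161), and CXCL8 was 1.25-fold higher on 1 of its 2 probe sets. Cytokines and growth factors had a median of -0.02 at percentile 44.6, with INHBA 1.57-fold lower and a log2 ratio of -0.47 at its second probe set. The genes of the IL-18 receptor and its signalling had a median of -0.02 at percentile 51.4. Its sign depended on the floor, as it was 0.03 with a floor at the 25th or 75th percentile. The main median is the floored ratio of MAP2K6, a gene outside the naming rule. The signals of MAP2K6 were 144.3 with siRNA-Tbet and 89.2 with siRNAc, so the floor turned its direction. The list stood apart as higher with the median over each gene's probe sets (0.09, percentile 99.1) and with second probe sets (0.23, percentile 99.75). IRAK2, a kinase of that pathway, was 1.23-fold lower on its brighter probe set and had 0.76 on the other. TAB1 was 1.22-fold lower, ATF2 was 1.19-fold higher with 3 of 3 probe sets on that side, and TOLLIP was 1.17-fold higher on a probe set that only 1 of its 3 others matched in direction.

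Lineage markers did not stand apart in the main setting either. Dendritic cell maturation genes had a median of -0.09 at percentile 14.03, but stood apart as lower with a floor at the 25th percentile (-0.21, percentile 0.70), with no floor (-0.21, percentile 0.61) and with only plain probe sets (-0.22, percentile 0.66). CCR7, a homing receptor, was 1.44-fold lower (594 against 857), LAMP3 at least 1.53-fold lower and CD207, the Langerhans cell lectin, at least 1.47-fold higher (215 against 57). Progenitor genes had a median of 0.04 at percentile 77.8, and 0.11 with a floor at the 25th percentile (percentile 98.8) or none (percentile 98.6). GATA2, a transcription factor of progenitors, was 1.37-fold higher (15712 against 11483) with 3 of 3 probe sets on that side. MYC was 1.22-fold higher, MYB was 1.27-fold higher on 1 probe set and had -0.32 on the other, and ETV6 was 1.18-fold lower on 1 of its 5 probe sets and higher on the others. Granulocyte and monocyte genes had a median of -0.03 at percentile 37.4; NCF1 was 1.65-fold lower on a probe set that can read its near-identical pseudogenes, LYZ was 1.41-fold lower, CSF1R was at least 1.52-fold lower and MPO, myeloperoxidase, was at least 1.43-fold higher (210 against 127). Markers of T and B lymphocytes had a median of -0.09 at percentile 18.8, with 9 of 20 higher and 11 lower, and the mean in place of the median was -0.22 at percentile 0.89. In that list CD2 was 1.96-fold lower (339 against 663), NCAM1 was 1.57-fold lower (550 against 862) with -0.68 on its second probe set, and CD4 was at least 2.34-fold lower (29 against 337). LAT, a T cell adaptor, had log2 ratios of -0.97 and 0.71 at its 2 probe sets. CD3D, the brightest member and outside the naming rule, was picked after its values were seen; it was 1.17-fold higher (16036 against 13657). Erythroid and megakaryocyte markers had a median of 0.06 at percentile 84.9, and the 3 probe sets of HBB disagreed in direction.

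Ribosomal protein and stress genes had higher signals with siRNA-Tbet. Of 36 measured cytosolic ribosomal protein genes, 35 were higher and 1 was lower, with a median log2 ratio of 0.14 (10.6% higher) at percentile 100. RPL24 had signals of 53930 and 45457. These are among the brightest transcripts, and after quantile normalization the median was 0.01 at percentile 91.4. It was 0.06 with the lowess trend removed and 0.11 at percentile 96.3 with second probe sets. Of 32 heat shock and endoplasmic reticulum stress genes, 23 were higher and 9 lower, with a median of 0.10 (7.3% higher) at percentile 99.97. The lowest member had a log2 ratio of -0.67, and the naming rule left out members on that side. DDIT3, which encodes the stress factor CHOP, was at least 2.57-fold higher (376 against 106), DDIT4 was 1.31-fold higher, ASNS, asparagine synthetase, 1.26-fold and TXNRD1 1.18-fold. The stress list no longer stood apart with second probe sets (percentile 90.5) or with only plain probe sets (percentile 97.96), and its median was 0.06 both with the lowess trend removed and after quantile normalization. Cell cycle genes had a median of -0.05 at percentile 1.6, with 25 of 43 lower and 18 higher, and fell short of the bound under 10 of 13 alternatives. The highest member had a log2 ratio of 0.38, and only lower members were open to naming. Within that list E2F1, a transcription factor of S phase entry, had log2 ratios of -0.59 and -0.43 at its 2 probe sets, CDT1 was 1.26-fold lower, and TOP2A was 1.24-fold lower (10674 against 13214) with 3 of 3 probe sets on that side.

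The remaining lists did not stand apart in the main setting. The medians were -0.06 for p53 target and apoptosis genes (percentile 23.1), 0.04 for immediate early genes (percentile 85.6), 0.05 for cholesterol synthesis genes (percentile 94.1), 0.05 for glycolysis and hypoxia genes (percentile 90.5) and 0.06 for oxidative phosphorylation genes (percentile 89.6). Cholesterol synthesis genes stood apart as higher with the median over probe sets (0.12) and second probe sets (0.16), and glycolysis genes with second probe sets (0.15). CDKN1A, the cell cycle inhibitor p21, was 1.29-fold lower (3304 against 4264), SESN1 was 1.28-fold lower, and PLK3 was 1.41-fold higher on 1 probe set and had -0.67 on the other. DUSP2, a phosphatase, was 1.52-fold higher (1195 against 786) and SPRY2 1.31-fold higher, while FOSL1 and SPRY4 were 1.49-fold lower. DHCR7, of cholesterol synthesis, was 1.17-fold higher, ADM, induced by hypoxia, was 1.49-fold lower and GPI, of glycolysis, 1.15-fold higher. Of the respiratory chain genes, SDHC was 1.17-fold lower with 7 of 7 probe sets on that side, and COX6C was 1.13-fold higher. The genes commonly used for normalization had a median of 0.08 at percentile 95.1, with ACTB at 69249 and 62100 and POLR2A 1.55-fold lower.

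The Affymetrix controls measured labelling and RNA integrity. The ratio of 3' to 5' probe sets was 1.20 with siRNA-Tbet and 1.22 with siRNAc for ACTB, and 0.975 and 1.01 for GAPDH, so RNA integrity by this measure was alike on both arrays. The bacterial transcripts added before hybridisation (bioB, bioC, bioD and cre) had median log2 ratios between -0.19 and 0.12. The poly-adenylated bacterial transcripts (lys, phe, thr, dap and trp) were all higher on the siRNA-Tbet array, by 4.43-fold for phe to 13.5-fold for lys.

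**Figure D3:**
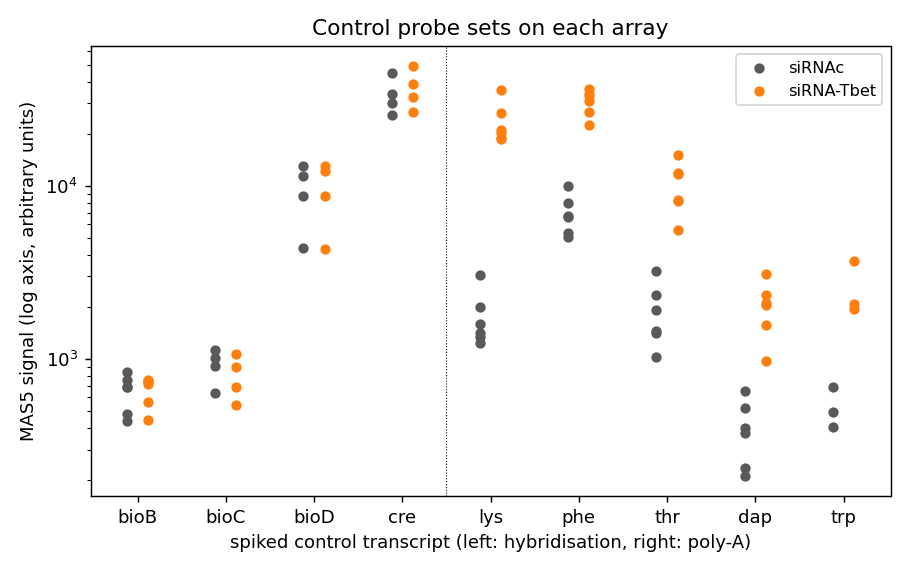
MAS5 signal (y axis, log scale, arbitrary units) of each probe set of the 9 spiked control transcripts (x axis) on the siRNAc array (grey) and the siRNA-Tbet array (orange), with 3 to 6 probe sets per transcript and 1 array per group. The 4 hybridisation controls overlap between arrays, while the 5 poly-A controls are 4.43-fold to 13.5-fold higher (medians) with siRNA-Tbet.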

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

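The tests in this part were chosen after the control signals had been seen. The poly-adenylated spike-in transcripts, which are not part of the gene comparisons, had higher signals on the siRNA-Tbet array than on the control array. The median log2 ratios of their probe sets were 2.36 for dap, 3.76 for lys, 2.15 for phe, 2.46 for thr and 2.35 for trp. A difference in scaling or hybridisation of the whole array is argued against by the 18 probe sets of the hybridisation controls, whose median log2 ratio was -0.0019 (range -0.41 to 0.36), below every poly-A probe set. One common factor, as would follow from a different dilution of a single spike mix or a different share of mRNA in the total RNA, is argued against as the whole explanation by lys: its 6 probe sets (3.55 to 3.93) lay above all 21 probe sets of the other poly-A controls (1.85 to 2.89), and the medians differed by 1.43. A difference in the composition of the spike mix, or in labelling batch, may remain, and nothing in the labels describes it; no biological explanation was tested for these bacterial sequences.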

How the results depend on the processing

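The alternative with each gene's second-brightest probe set was chosen after seeing the data, and the others were fixed in advance. No paired analysis was possible because each group holds 1 array, and no replicate could be left out. The TBX21 log2 ratio was -0.94 with median scaling and -0.95 with quantile normalization or the lowess trend removed; the other 6 alternatives could not move it, as its 1 probe set lies above every floor. The counts of 2-fold genes depended on the floor: 860 higher and 791 lower with a floor at the 25th percentile, 1873 and 1780 with no floor or filter, and 0 and 0 with a floor at the 75th percentile, so dim probe sets set these counts. At 1.5-fold they were 238 higher and 360 lower, at 3-fold 1 and 0, and with second probe sets 23 were higher and 22 lower, among the 6122 genes that have one. Of 299 list values under alternatives, 267 stayed on their side of the bounds, and no list that stood apart turned to the other side. Median scaling shifts all ratios alike and could not change a percentile, so its values add nothing to that count. The alternatives in which a list crossed a bound follow, with its median log2 ratio; the cause was not tested. Th1 and natural killer effector genes no longer stood apart with a floor at the 75th percentile (-0.049), with only plain probe sets (-0.050) and with second probe sets (-0.0034). The interferon-γ list missed the bound without signal matching (-0.099, percentile 2.31) and with second probe sets (-0.097), and the type I list with second probe sets (-0.081). Cell cycle genes missed it with quantile normalization (-0.061), the lowess trend removed (-0.049), a floor at the 25th percentile, no floor, any suffix, 5 bins or no matching (-0.045 in each), the median over probe sets (-0.037), only plain probe sets (-0.072) and the mean (-0.041). Heat shock and stress genes missed it with only plain probe sets (0.077) and second probe sets (0.091), and ribosomal protein genes with quantile normalization (0.0073) and second probe sets (0.11). Lists that stood apart only under an alternative were higher for IL-18 receptor genes (0.094 with the median over probe sets, 0.23 with second probe sets), progenitor genes (0.11 with a floor at the 25th percentile or none), cholesterol synthesis genes (0.12 with the median over probe sets, 0.16 with second probe sets), Th2 and Th17 genes (0.33 with second probe sets, 4 genes) and glycolysis genes (0.15 with second probe sets). They were lower for dendritic cell genes (-0.21 with a floor at the 25th percentile or none, -0.22 with only plain probe sets) and for T and B lymphocyte markers (-0.22 with the mean). Of 1051 values of 119 named genes, 966 moved by less than the technical spread, 85 moved by more, and 30 had the other sign. Of those that moved by more, 31 were among the 51 values from second probe sets. Most other alternatives mostly kept a gene's probe set, so many values could hardly move and the count of 966 overstates stability. With the brightest probe set of any suffix, only 2 of 119 values moved by more, and with a floor at the 25th percentile 3 of 119. Signal over background limits the dim genes, where the technical spread reached 0.41.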

Other observations

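The tests on second probe sets, on agreement between probe sets and on families by symbol, and the count of arrays, were chosen after the main results had been seen; the trend corrections were fixed in advance, but their use to weigh these lists was chosen after their results were seen. Several genes, all but CASP1 outside the lists, differed the same way at 3 or more probe sets, and were picked after their values were seen. The vesicle protein gene SCAMP1 (6 probe sets) had a median over its probe sets 2.31-fold higher with siRNA-Tbet, the kinase gene HIPK3 2.16-fold, LSM14A, an RNA granule protein, 1.71-fold, and PTBP3, a splicing regulator (5 probe sets), 1.54-fold. Lower with siRNA-Tbet were RBMS1, an RNA-binding protein (6 probe sets, 1.68-fold), CLEC7A, which encodes the β-glucan receptor dectin-1 (1.57-fold), LACC1, a macrophage enzyme (1.56-fold), and CASP1, the inflammasome caspase and a member of the interferon-γ response list (5 probe sets, 1.26-fold).

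Of 2928 genes with 3 or more measured probe sets, 26 had all of them at least 0.3 apart on the log2 scale in the same direction, 15 higher and 11 lower. In 100 shuffles of the ratios within signal deciles the median count was 8 and the highest 15, so agreement of probe sets by chance alone does not account for the count. Probe sets of a gene can share probes and are read on the same 2 arrays, so these genes may differ between the 2 RNA samples without depending on T-bet. Whether either siRNA acts on them directly was not tested, as its sequence was not used here.

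Among 114 groups of at least 12 measured genes that share a symbol stem, 5 lay at percentile 1 or lower or 99 or higher. For groups of unrelated genes, 2.28 would be expected by chance. The RPL and RPS groups share 20 of 40 and 14 of 33 genes with the ribosomal list, and the RPS stem also takes in S6 kinase genes. Without both groups 3 of 112 groups remain against 2.24 by chance, so that count is close to chance. They were the MRPS genes of the small mitochondrial ribosomal subunit (27 genes, 19 higher, median log2 ratio 0.09, percentile 99.9), the ZNF zinc finger genes (395 genes, 201 higher, median 0.01, percentile 99.8) and the DDX helicases (31 genes, median 0.07, percentile 99.01). After quantile normalization the percentiles were 99.9 for MRPS, 99.5 for ZNF, 91.7 for DDX, 95.6 for RPL and 61.7 for RPS.

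The lower signals of the Th1, type I interferon and interferon-γ lists are open to more than one reading. A signal-dependent trend between the arrays is argued against by the medians with the lowess trend removed, which were -0.19, -0.12 and -0.09. The highest percentile of the 3 lists was then 0.29. The random lists were already matched on signal, so that percentile adds little on a trend. Errors of single probe sets stay open: over second probe sets the percentile was 49.0 for 13 Th1 and natural killer genes (median -0.0034), 2.19 for 18 interferon-γ genes (median -0.10) and 4.04 for 22 type I genes (median -0.08), so the Th1 list has no support there while both interferon lists keep their direction. A candidate explanation is that less T-bet gave less interferon-γ and so a weaker interferon response, in which IFNG itself was 11.1% lower. It cannot be told apart from any other difference between the cultures or arrays, since there was 1 array per group. The cultures also differed in the siRNA they received. Replicate arrays with these siRNAs would therefore not separate less T-bet from other effects of either siRNA, such as an interferon response to transfected RNA, which was not tested.

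The higher signals of the ribosomal protein and the heat shock and stress lists were weighed in the same way. For the stress list a signal-dependent trend is argued against as the whole cause, since the lower of its percentiles after lowess and quantile correction was 99.3, but the median went from 0.101 to 0.058 and 0.059, so a trend may account for part of it. For the ribosomal list a trend stays open. Quantile normalization, which pulls the brightest signals of both arrays together, took the median from 0.14 to 0.01, at percentile 91.4. With the lowess trend removed the median was 0.061 at percentile 99.89. Among other bright transcripts, ACTB (log2 ratios 0.12 to 0.16 at 3 probe sets) and the GAPDH controls (0.12 to 0.17) were higher by similar amounts, but GBP1 (0.0044 at its brightest probe set) was not. The top signal bin holds both BHLHE40 (9634 against 11407) and ACTB (69249 against 62100), so random lists were matched only coarsely within it. Errors of single probe sets stay open for both lists, with percentiles over second probe sets of 96.3 for 21 ribosomal genes (median 0.11) and 90.5 for 19 stress genes (median 0.09). A response to the T-bet siRNA could also give such differences, which 1 array per group leaves untested.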
